A study of Mus musculus with 6 samples.

How the data were processed

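RNA was extracted from organoids and made into directional polyA libraries, per the labels' protocols. The data used here are 1 table of the whole series with a raw read count per gene in each of 6 libraries, per the file headers, together with the authors' p-value, FDR, log2 fold change and shrunken log2 fold change for retinoic acid against vehicle. The table's heading gives these statistics as coming from DESeq, per the file headers, and the FDR equals a Benjamini-Hochberg adjustment of the deposited p-value over all rows. Reads were aligned to the mouse build mm10, per the submitters' processing notes. The aligner, the gene annotation, the treatment of reads that match several places and whether counting used strand are not given in the sources used here. The table has 21534 rows, and 21102 of them have an Ensembl gene ID found in the reference's table of gene names. Current symbols were taken from there, which replaced the file's symbol in 2158 rows (Ostb became Slc51b, Osta Slc51a, Clca3 Clca1, Ctgf Ccn2, 1810030J14Rik Mptx1 and 2210415F13Rik Lypd8). There were 32 gene IDs on more than 1 row (67 rows), which were kept as deposited. Coordinates are those of the table. The mitochondrial share of reads was not analysed here.

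Groups and replicate numbers came from the sample titles, and columns were matched to samples by name. Replicates of a group were compared by a chi-square statistic of their counts. It was between 4.09 and 11.07 per row for pairs of libraries of 1 group, above the value near 1 that sampling noise gives, so no library was counted as a repeat of another.

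Counts were analysed with edgeR 4.0.16 in R 4.3.3. Rows with low counts were removed with filterByExpr at its defaults, leaving 13700 rows, which held at least 99.89% of each library's reads. Libraries were scaled with TMM (factors 0.978 to 1.023). A quasi-likelihood model with treatment as its only term (glmQLFit and glmQLFTest) was fitted to all 6 libraries, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The tests are two-sided. The standard error of a log2 fold change is its size divided by the square root of the F statistic. It thus comes from the test and not from the printed SDs. For very large changes from a low vehicle level, such as those of Cyp26b1 and Fabp6, it may be too small. The biological coefficient of variation was 7.8%, and the median log2 fold change of the tested genes was −0.008. CPM are counts per 1000000 of the TMM-scaled library size.

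The main test, the alternatives, 28 gene lists and the rule for named genes were fixed before the data were examined. The lists cover retinoid targets and handling, epithelial cell types, signalling pathways, metabolism, defence, stress, and markers of other cell types. In all they hold 703 genes, of which 676 are in the table and 540 were tested. Lists with at least 5 tested members (25 of 28) were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, and p-values were adjusted over the 25 lists. Camera asks whether a list's genes moved on balance in one direction relative to other genes, so a list whose genes moved both ways may not be called. No list passed the threshold with an estimated correlation. Fry, run as an alternative, asks whether a list's genes moved on balance in one direction and does not compare them with other genes.

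Named genes are of 3 kinds by the rule. The first is the 10 largest increases and the 10 largest decreases among called genes with a mean of at least 1 CPM and no overlap between the groups' libraries, leaving out predicted and unnamed gene models. The second is a fixed set of 21 markers (Cyp26a1, Cyp26b1, Rarb, Dhrs3, Isx, Lgr5, Ascl2, Olfm4, Axin2, Mki67, Apoa4, Alpi, Muc2, Lyz1, Chga, Neurog3, Dclk1, Ly6a, Clu, Hes1 and Atoh1). The third is up to 4 further called members of each list, those with the smallest p. Another 16 genes that complete small counts were named after their values were seen, and are said to be so where they appear. Apob was also named after its value was seen, and is not among the named genes counted later. A few genes that the rule takes are not reported here.

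The steps were tested on simulated counts of the 13700 genes for this comparison. Of 99 genes changed 1.5-fold 68.7% were called, of 100 changed 2-fold 93% were called, 3.01% of the 166 calls were unchanged genes, and every called changed gene had the right sign. With no list changed 0 of 25 lists were called, and a cell cycle list lowered 1.25-fold was called with no other list. The simulated genes varied independently, so this says nothing about lists of correlated genes.

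The alternatives were DESeq2 size factors within edgeR, no filter on low counts, another filter of at least 10 counts in every library of at least 1 group (13461 genes, without 262 of the 13700 and with 23 others), DESeq2 1.42.0 (Wald test), limma-voom, a test against a 1.5-fold change (glmTreat), a block on replicate number, and leaving out each library in turn. For the lists they also included an estimated correlation and fry. Leaving out both libraries numbered 3, and summing rows that are segments of 1 gene, were chosen after seeing the data.

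The depth of 14919144 to 21833846 counts leaves genes under about 1 CPM with few counts, and their fold changes are uncertain. Genes that overlap another on the opposite strand are uncertain because the use of strand in counting is not given. Among the named genes these include Slc51b, Cav1, Lgr5, Axin2, Apoa4, Neurog3, Lrat, Adh1, Ccn2, Ace, Maf, Bcas1, Notch1, Duoxa2, Irf1, Hadha, Gata5, Hnf4a, Ddc, Mmp7, Prap1 and Ttr. Reads may be shared between copies for Acot1 and Acot2, Lyz1, Ang4, Ly6a, Krt6a, Krt14, Cyp2b10, the Cyp2c, Cyp2d and Cyp2j genes, Gsta4, Mptx1 and Akr1c14. GC content and length of each gene's longest transcript, used in the closing section, came from GENCODE's mouse transcripts of the same genome assembly. Figures were drawn with matplotlib.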

Results

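Polyadenylated RNA was sequenced from intestinal organoids grown from the ileum of wild-type C57Bl/6 mice. Such organoids are closed epithelial cultures that hold stem cells and their descendants. Before treatment they were kept for 96 hours in medium with 10 µM CHIR99021, an inhibitor of the kinase GSK3 that activates Wnt signalling and enriches for stem cells. They then received 10 µM retinoic acid, the active form of vitamin A, or vehicle (DMSO) for 24 hours. There were 3 vehicle and 3 retinoic acid libraries. The total read count over genes was 16927696, 16592854 and 14919144 in vehicle libraries 1, 2 and 3, and 21833846, 15080190 and 20141393 in retinoic acid libraries 1, 2 and 3. The first principal component held 44.8% of the variance and separated the treatments, and the second held 20% and set library 3 of each group apart from the other 4 libraries. The labels do not say whether libraries of a group came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical.

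The comparison asked which transcripts respond to retinoic acid in stem cell-enriched epithelium. The largest increase was in Cyp26b1, which encodes an enzyme that breaks down retinoic acid (ENSMUSG00000063415, mm10 chromosome 6, 84571414 to 84593908). It went from 0.852 ± 0.482 to 921 ± 174 CPM (counts per 1000000 of the TMM-scaled library size, mean ± SD, n = 3 in each group). This was a 1070-fold difference, with a log2 fold change of 10.07 (9.71 to 10.6 with 1 library left out) and a standard error (SE) of 0.22. The vehicle mean lay under 1 CPM, so the size of the fold is uncertain. Next came Fabp6, the ileal bile acid-binding protein, at 224-fold, and Fabp1, a fatty acid-binding protein of enterocytes, at 26.3-fold. Both also had a vehicle mean under 1 CPM, so these folds are uncertain too. Of 13700 genes tested, 736 were higher and 560 lower with retinoic acid at a Benjamini-Hochberg adjusted p under 0.05 in edgeR's quasi-likelihood test. Most of these changes were small: 102 of the higher and 51 of the lower genes differed by at least 2-fold, and the median absolute log2 fold change of called genes was 0.45. All libraries of one group lay above all of the other for 25.5% of the tested genes, where chance gives 10%. Leaving out vehicle library 1 gave 477 higher and 355 lower genes, leaving out vehicle library 2 gave 528 and 346, and leaving out retinoic acid library 1 gave 443 and 289. The authors' deposited table, made from the same counts, lists 714 higher and 458 lower genes at an FDR under 0.05, and 1123 of these were called here with the same sign.

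**Figure D1:**
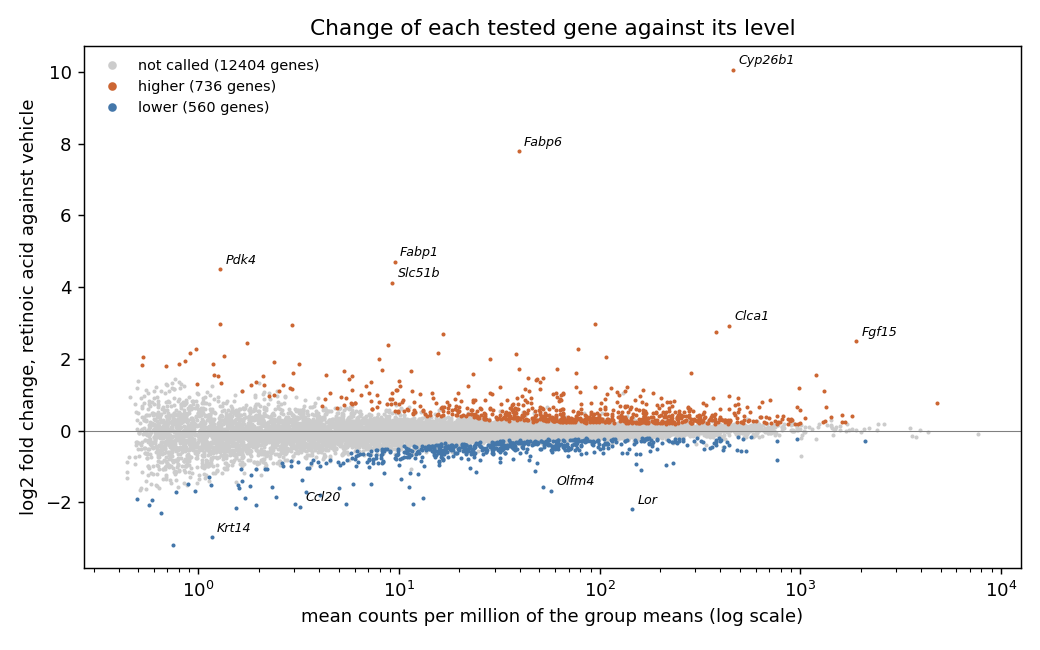
Log2 fold change of each of the 13700 tested genes (retinoic acid against vehicle, vertical axis) against its mean level in CPM (horizontal axis, log scale), with called genes in colour. The 736 higher and 560 lower genes lie mostly within 2-fold, and Cyp26b1 and Fabp6 stand above all other genes.

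Among known targets of retinoic acid receptors, 4 of 13 tested members rose and 2 fell (7 and 3 adjusted over the list alone), and camera called the list higher at an adjusted p of 0.00115 (adjusted p = 0.12 with an estimated correlation). The 4 were Cyp26b1, Dhrs3, Isx and Nrip1. Dhrs3, which reduces retinaldehyde to retinol, rose 4.39-fold from 14.1 ± 2.03 to 62.1 ± 11 CPM (SD, n = 3). Isx, an intestinal transcription factor that represses vitamin A uptake genes, rose 6.76-fold from 97.8 ± 28.8 to 660 ± 27.2 CPM. Nrip1, a nuclear receptor corepressor, had a log2 fold change of 0.31 (SE 0.06). The 2 that fell were Lrat, which esterifies retinol (log2 fold change −2.16, SE 0.60), and Cdx1, an intestinal homeobox gene (−0.35, SE 0.09). The adjusted p of Lrat was 0.0353 and became 0.235 without vehicle library 2, 0.0651 without vehicle library 1 and 0.114 without retinoic acid library 2; its log2 fold change was −3.40 without retinoic acid library 1 and −1.43 without vehicle library 2. Cdx1 lost its call without vehicle library 2 or 3 or without retinoic acid library 1 or 2 (adjusted p up to 0.125). The number of lower members was 1 without vehicle library 1 or retinoic acid library 1 and 0 without vehicle library 2 or retinoic acid library 2. The retinoic acid receptor gene Rarb had 0.462 ± 0.207 CPM with vehicle and 1.04 ± 0.249 CPM with retinoic acid and was not called (adjusted p = 0.142). Cyp26a1, a close relative of Cyp26b1, had 9 counts over the 3 vehicle libraries and 1 count over the 3 retinoic acid libraries, too few to be tested.

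Genes of vitamin A handling went both ways, with 6 of 24 higher and 3 lower (9 and 7 adjusted over the list alone), and the list was not called by camera (adjusted p = 0.132), though fry, which tests a list on its own and not against other genes, called it higher (adjusted p = 0.0123). Adh4, an alcohol dehydrogenase that oxidises retinol, rose 7.83-fold, and Adh1 rose 2.02-fold. The receptor genes Rarg and Rara rose 1.44-fold and 1.19-fold. Scarb1, a receptor through which carotenoids enter cells, fell by 1.04 on the log2 scale (SE 0.16). Ttr, the plasma carrier of retinol-binding protein, was the third member to fall (−1.07, SE 0.32), and was named after its value was seen. Without vehicle library 2 or retinoic acid library 1 the list was called higher (adjusted p = 0.0401 and 0.038). The call of Rara was lost without 4 of the 6 libraries in turn (adjusted p up to 0.147), and that of Ttr without 5 of them (up to 0.195). The 3 lower members became 1 without vehicle library 2 or retinoic acid library 2.

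Genes of ileal bile acid handling showed some of the largest increases: 5 of 9 tested members rose and 1 fell (6 and 2 adjusted over the list alone). Fabp6 (ENSMUSG00000020405, mm10 chromosome 11, 43596049 to 43601540) rose from 0.341 ± 0.0717 to 78.6 ± 13.4 CPM (SD, n = 3). Its log2 fold change was 7.80 (SE 0.21), and both are uncertain because the vehicle mean lay under 1 CPM. Fgf15, the hormone through which the ileum represses bile acid synthesis in the liver (ENSMUSG00000031073, mm10 chromosome 7, 144896532 to 144900953), rose 5.66-fold from 568 ± 12.2 to 3210 ± 259 CPM. Slc51a and Slc51b, the subunits of the basolateral bile acid exporter, rose 6.44-fold and 17.5-fold, and the exporter gene Abcc3 rose 1.45-fold. Slc10a2, the apical transporter that takes bile acids up from the lumen, fell by 0.41 on the log2 scale (SE 0.09); 2 members were lower without vehicle library 1. Camera called the list higher at an adjusted p of 0.00027 (adjusted p = 0.12 with an estimated correlation).

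**Figure D2:**
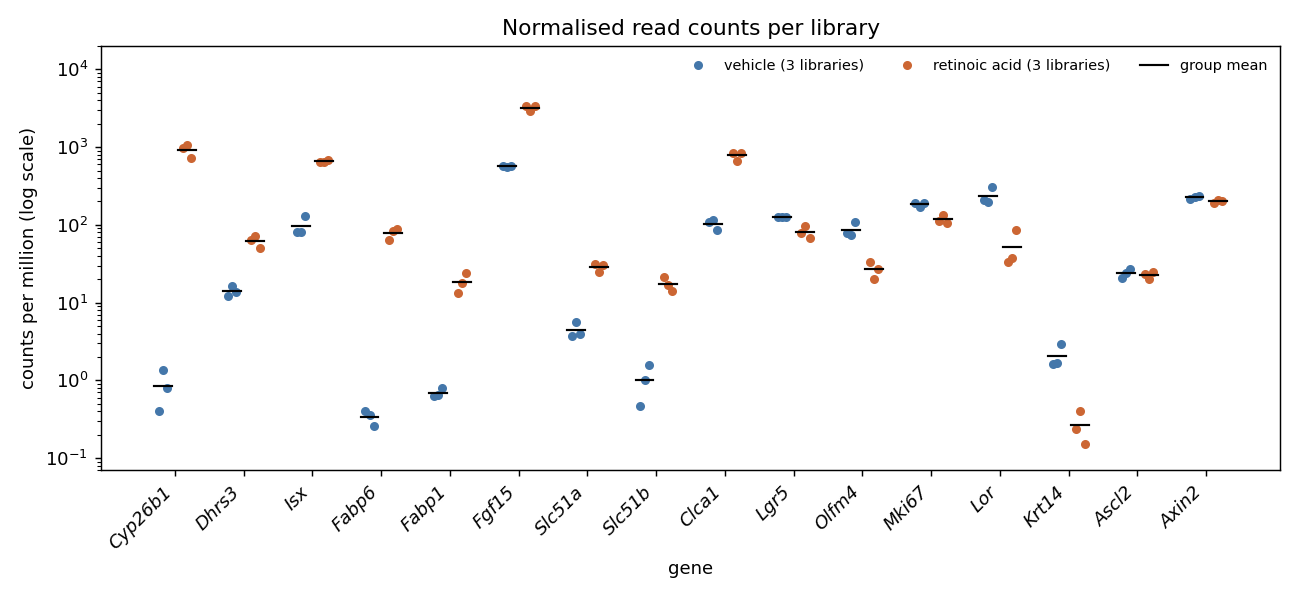
Read counts in CPM (log scale) of 16 genes in each of the 3 vehicle and 3 retinoic acid libraries, with group means as bars. For Cyp26b1, Fabp6, Fgf15, Slc51a and Slc51b every retinoic acid library lies above every vehicle library, while Ascl2 was not called (adjusted p = 0.79).

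In the list of fatty acid oxidation genes and PPAR targets 14 of 27 tested members were higher and none lower (19 and 2 adjusted over the list alone), and the other 13 were not called. Camera called the list higher at an adjusted p of 4.52e-11 (adjusted p = 0.12 with an estimated correlation). Fabp1 rose from 0.692 ± 0.0847 to 18.3 ± 5.31 CPM (SD, n = 3). Pdk4, a kinase that restrains glucose oxidation, rose 22.6-fold, from 5 counts over the vehicle libraries to 135 over the retinoic acid libraries. Cpt1a, which admits fatty acids to mitochondria, rose 1.64-fold, and Hadha, a subunit of the mitochondrial beta-oxidation complex, rose 1.52-fold. The thioesterases Acot1 and Acot2 rose 4.49-fold and 2.64-fold, but these neighbouring genes are near-identical copies, so the split of reads between them is uncertain. Outside this list, Acacb, the mitochondrial acetyl-CoA carboxylase, rose 7.73-fold. The cholesterol synthesis list was not called (adjusted p = 0.21), with 4 of 25 members higher and none lower (4 and 1 adjusted over the list alone). These were Hsd17b7, Insig1, Pmvk and Sqle, each raised by at most 1.30-fold and each losing its call without at least 1 library (adjusted p up to 0.164). Their number was 1 without vehicle library 1, 2 without vehicle library 2 or retinoic acid library 2, and 0 without retinoic acid library 1.

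Drug-metabolising genes split, with 12 of 33 higher and 5 lower (14 and 6 adjusted over the list alone). The higher ones numbered 5 without vehicle library 1 and 6 without retinoic acid library 2, and the lower ones 8 without retinoic acid library 3. Nqo1, a quinone reductase, rose 1.81-fold, the exporter gene Abcc2 rose 1.48-fold and the glutathione transferase gene Gsta4 rose 1.40-fold. The 5 that fell were cytochrome P450 genes. Cyp2b10 fell by 2.04 on the log2 scale (SE 0.33) and Cyp2c55 by 0.90 (SE 0.10). Cyp2d26 (−0.78), Cyp2j6 (−0.59) and Cyp3a13 (−0.30) were named after their values were seen, and Cyp3a13 lost its call without 4 of the 6 libraries in turn (adjusted p up to 0.171). The list was not called (adjusted p = 0.0714), but was called higher without vehicle library 2 (0.021), retinoic acid library 1 (0.0339) or retinoic acid library 2 (0.0473). Fmo5, a flavin monooxygenase outside the list, rose 7.90-fold from 21.4 ± 4.47 to 169 ± 15.3 CPM (SD, n = 3).

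Cell cycle genes fell together. Of 36 tested S phase and mitotic genes 24 were lower and none higher (31 and 0 adjusted over the list alone), with a median log2 fold change of −0.47. Mki67, the gene of the proliferation marker Ki-67, went from 184 ± 13.6 to 118 ± 15.2 CPM (SD, n = 3; log2 fold change −0.65, SE 0.09). The replication helicase genes Mcm6, Mcm5 and Mcm2 had log2 fold changes of −0.70, −0.61 and −0.53, and Rrm2, a subunit of ribonucleotide reductase, had −0.61. Camera called the list lower at an adjusted p of 1.96e-17 (adjusted p = 0.12 with an estimated correlation).

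Markers of crypt base columnar stem cells were also lower, in 10 of 24 tested members, with 1 higher (12 and 1 adjusted over the list alone). Olfm4 fell by 1.67 on the log2 scale (SE 0.16), from 87 ± 18.1 to 27 ± 6.44 CPM (SD, n = 3). Lgr5, the R-spondin receptor that marks these cells (ENSMUSG00000020140, mm10 chromosome 10, 115450311 to 115587780), went from 127 ± 1.38 to 81.7 ± 15 CPM (log2 fold change −0.64, SE 0.10). Slc12a2, Smoc2, Kcne3 and Rgmb had log2 fold changes of −0.82, −0.63, −0.61 and −0.36. The stem cell transcription factor gene Ascl2 was not called, at 23.9 ± 3.31 and 22.7 ± 2.19 CPM, and the 1 member that rose was Ephb2, an ephrin receptor (1.19-fold), where 2 rose without vehicle library 1 and 3 without retinoic acid library 3. Camera called the list lower at an adjusted p of 6.28e-06 (adjusted p = 0.12 with an estimated correlation).

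Wnt targets as a list were not called by camera (adjusted p = 0.259) but were called lower by fry (adjusted p = 0.031), with 1 of 25 members higher and 4 lower (1 and 4 adjusted over the list alone). The 4 were Lgr5, Ephb3 (−0.39), Apcdd1 (−0.66) and Sox4 (−0.20), and the call of Sox4 was lost without 4 of the 6 libraries in turn (adjusted p up to 0.195). Lgr5, Ephb3 and Ephb2, the member that rose, are also in the stem cell list, so these lists are not separate evidence. Axin2, a feedback inhibitor of the pathway, had 226 ± 11.7 and 201 ± 7.83 CPM (SD, n = 3) and was not called (adjusted p = 0.101). In the Notch list 5 of 17 members fell and none rose (5 and 0 adjusted over the list alone), and camera called the list lower at an adjusted p of 0.00904 (adjusted p = 0.157 with an estimated correlation). The 5 were the receptor gene Notch1 (log2 fold change −0.64), the ligand genes Dll1 (−0.61) and Jag1 (−0.30), the target Nrarp (−0.31) and Hes6 (−0.24), the last named after its value was seen. Hes1, a main Notch effector, was not called (adjusted p = 0.613). The list's call was lost without vehicle library 2 (adjusted p = 0.0567), and of these genes Notch1 alone stayed called whichever library was left out (adjusted p up to 0.203 for the other 4). The number of lower Notch list members was 3 without vehicle library 1 or retinoic acid library 2, 2 without vehicle library 2 and 1 without retinoic acid library 1.

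Paneth cell genes were lower in 10 of 19 members and higher in 1 (14 and 1 adjusted over the list alone), with a median log2 fold change of −0.37. Without vehicle library 1 or retinoic acid library 1 the number of lower members was 6. Reg4, a lectin also found in enteroendocrine and goblet cells, fell by 0.96 on the log2 scale (SE 0.10), Mptx1 by 1.34 (SE 0.22), Cd24a by 0.56 (SE 0.08) and the antimicrobial ribonuclease gene Ang4 by 0.48 (SE 0.07). Mmp7, a protease that activates defensins, was the 1 member that rose (0.63, SE 0.11) and was named after its value was seen. Camera called the list lower at an adjusted p of 1.95e-07 (adjusted p = 0.12 with an estimated correlation). Lyz1, the Paneth cell lysozyme, had 3790 ± 146 and 3380 ± 161 CPM (SD, n = 3) and was not called (adjusted p = 0.072), though it was without retinoic acid library 3 (0.0206).

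Of 22 goblet cell genes 4 fell and 1 rose (6 and 1 adjusted over the list alone). The riser was Clca1, a secreted mucus component, at 7.55-fold (104 ± 14.9 to 783 ± 97.3 CPM; SD, n = 3). Agr2 (log2 fold change −0.50), Bcas1 (−0.66), Capn9 (−0.88) and Spdef (−0.30) fell, and each lost its call without at least 2 of the libraries in turn (adjusted p up to 0.142). The number of lower members was 0 without vehicle library 1 or 2, 1 without retinoic acid library 1, 2 without retinoic acid library 2 and 7 without library 3 of either group, and 2 were higher without retinoic acid library 3. The list was called lower (adjusted p = 0.0256), which was lost without vehicle library 1 (0.148), with an estimated correlation (adjusted p = 0.514) and with fry, which tests a list on its own (adjusted p = 0.505). The mucin gene Muc2 was not called (adjusted p = 0.161), but was without retinoic acid library 3 (log2 fold change −0.41, adjusted p = 0.00116). Atoh1, the transcription factor gene of the secretory lineage, was not called (adjusted p = 0.143), but was without vehicle library 3 (0.0297).

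The enteroendocrine list was not called (adjusted p = 0.113), with 3 of 35 members higher and 4 lower (3 and 4 adjusted over the list alone), but was called lower without vehicle library 3 (7.08e-05) or retinoic acid library 1 (0.0245). The hormone gene Pyy rose 2.16-fold, Ddc 1.36-fold and Sst, the somatostatin gene named after its value was seen, by 0.67 on the log2 scale. The progenitor transcription factor genes Insm1 (−0.49) and Neurog3 (−0.40), with Reg4 and Vwa5b2 (−0.78, named after its value was seen), fell. The calls of Neurog3 (adjusted p = 0.0353), Sst and Vwa5b2 were lost without some of the libraries in turn (adjusted p up to 0.108, 0.196 and 0.0795), that of Neurog3 whichever library was left out, and 2 members were lower without vehicle library 1 or 2. Chga, a general enteroendocrine marker, was not called (adjusted p = 0.695). The tuft cell list was not called (adjusted p = 0.613). Of its 19 members 1, the prostaglandin synthase gene Ptgs1, fell (1.79 on the log2 scale; 0 higher and 1 lower adjusted over the list alone), and Dclk1 was not called (adjusted p = 0.385). The M cell list was not called (adjusted p = 0.822), and its median of 0.01, its mean of −0.23 and its upward test differ in sign. Of its 11 members Tnfaip2 (1.94-fold) and Relb (1.21-fold) rose and Ccl20 and Marcksl1 (−0.28) fell (3 and 3 adjusted over the list alone); Relb and Marcksl1 lost their calls without some 1 library (adjusted p up to 0.129 and 0.0524), and 1 member was higher without vehicle library 1 or 2 or retinoic acid library 1.

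Absorptive enterocyte genes went both ways, with 4 of 41 higher and 8 lower (7 and 14 adjusted over the list alone), and the list was not called (adjusted p = 0.315). Besides Fabp1, the higher ones were the lipid-handling genes Fabp2 (0.60 on the log2 scale) and Mttp (0.52) and the secreted protein gene Prap1 (0.45), all 3 named after their values were seen; Prap1 lost its call without some 1 library (adjusted p up to 0.147). Among the lower ones were brush border enzymes: the peptidase genes Ace (−1.21, SE 0.21) and Mep1a (−0.79, SE 0.14) and the alkaline phosphatase gene Alpi (−0.83, SE 0.17), together with the transcription factor gene Maf (−0.50). Apob, another lipid-handling gene, was lower too (−0.40, SE 0.08), and was named after its value was seen. Apoa4, an apolipoprotein of mature enterocytes, was not called, at 22.9 ± 7.25 and 22.1 ± 9.98 CPM (SD, n = 3). Without vehicle library 1 or retinoic acid library 3 the list was called lower (adjusted p = 0.0393 and 0.0241), and without the latter 5 members were higher and 17 lower. Without a filter on low counts 9 of 42 members were higher and 16 lower. With a block on replicate number 8 of 41 were higher and 16 lower.

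Positional regulators were not called as a list (adjusted p = 0.315), with 3 of 30 higher and 3 lower (3 and 7 adjusted over the list alone). Besides Isx, the transcription factor genes Gata5 (1.35-fold) and Hnf4a (1.18-fold) rose, and Cdx1 and Hnf4g (−0.23, named after its value was seen) were among those that fell; Hnf4a, Cdx1 and Hnf4g lost their calls without some 1 library (adjusted p up to 0.197). The 3 lower members became 1 without vehicle library 1, 0 without vehicle library 2 or retinoic acid library 1, and 6 without retinoic acid library 3. The list of colon and stomach markers was not called (adjusted p = 0.349), with 2 of 6 higher and none lower (3 and 1 adjusted over the list alone): the carbonic anhydrase gene Car2 (1.76-fold) and the chloride exchanger gene Slc26a3 (1.84-fold).

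Epithelial defence genes rose in 8 of 21 members and fell in 3 (9 and 3 adjusted over the list alone). Lypd8, which keeps flagellated bacteria off the epithelium, rose 2.93-fold from 608 ± 18.6 to 1780 ± 55.8 CPM (SD, n = 3). Duoxa2, the maturation factor of a hydrogen peroxide-producing oxidase, rose 3.00-fold, the immunoglobulin transporter gene Pigr 1.57-fold and Nos2, the inducible nitric oxide synthase, 1.55-fold. The 3 that fell were Ccl20, Reg3b (−1.53) and Ccl28 (−0.62), the last 2 named after their values were seen. Ccl28 lost its call without some 1 library (adjusted p up to 0.192). DESeq2's Wald test called 8 members higher and 1 lower. Camera called the list higher at an adjusted p of 0.0358 (adjusted p = 0.168 with an estimated correlation), and the call was lost without vehicle library 1 (0.0732) or vehicle library 3 (0.077). Interferon response genes were higher in 3 of 27 members and lower in none (3 and 0 adjusted over the list alone): Irf1 (1.37-fold), Oas3 (2.40-fold) and Oasl2 (1.73-fold). Camera called that list higher at an adjusted p of 0.00155 (adjusted p = 0.12 with an estimated correlation); the calls of Oas3 and Oasl2 were each lost without some 1 library (adjusted p up to 0.0618 and 0.0813), and 1 member was higher without vehicle library 1 and 6 without retinoic acid library 3. Besides these lists, that of leukocyte markers was also called higher (adjusted p = 0.0358, and 0.169 with an estimated correlation), with Cd14 at 1.34-fold and Cd68 at 1.69-fold. Its adjusted p was 0.0967 without vehicle library 1, 0.0662 without retinoic acid library 3 and 0.0634 with a block on replicate number.

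The fetal and regenerative epithelium list had 7 of 29 members higher and 2 lower (8 and 2 adjusted over the list alone). Sprr1a, a cornified envelope gene, rose 3.04-fold, Ccn2, a Yap target, 2.06-fold, and the growth factor genes Areg and Ereg 1.57-fold and 1.45-fold. Ly6a, which encodes Sca-1, rose 1.35-fold, and Clu 1.32-fold (adjusted p = 0.00789, and 0.0512 without retinoic acid library 1). Anxa1 (−0.48) and S100a6 (−0.32) fell and were named after their values were seen; S100a6 lost its call without some 1 library (adjusted p up to 0.106), and 1 member was lower without vehicle library 1 or 3 or retinoic acid library 1 or 2. The list was called higher (adjusted p = 0.028), with a median of 0.02, and the call was lost without vehicle library 3 (0.0843) or retinoic acid library 3 (0.106) and with an estimated correlation (adjusted p = 0.459). Stress response genes were higher in 6 of 24 members and lower in none (7 and 0 adjusted over the list alone), with an adjusted p of 0.00212 for the list (adjusted p = 0.169 with an estimated correlation). Among them were Hmox1, heme oxygenase (1.83-fold), the chaperone gene Hspa5 (1.28-fold) and the immediate early genes Egr1 (1.31-fold) and Fos (1.26-fold, with adjusted p up to 0.0874 without some 1 library). The 6 became 3 without vehicle library 2 or retinoic acid library 1. The p53 and apoptosis list was not called (adjusted p = 0.154; 0.0344 without retinoic acid library 2), with 4 of 21 higher and none lower (5 and 1 adjusted over the list alone), among them Gdf15 (1.42-fold), the cyclin-dependent kinase inhibitor gene Cdkn1a (1.33-fold) and Tnfrsf10b (1.33-fold); 2 members were lower without retinoic acid library 3. In the TGF-beta and BMP list (adjusted p = 0.831) 2 of 19 members, Ccn2 and Skil (1.18-fold, lost without 5 of the 6 libraries in turn, adjusted p up to 0.227), rose and none fell (2 and 3 adjusted over the list alone); its median of 0.03 was above 0 and its mean of −0.08 and its test were below. Without retinoic acid library 3, 4 members were higher and 2 lower, and without any other 1 library 1 was higher.

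**Figure D3:**
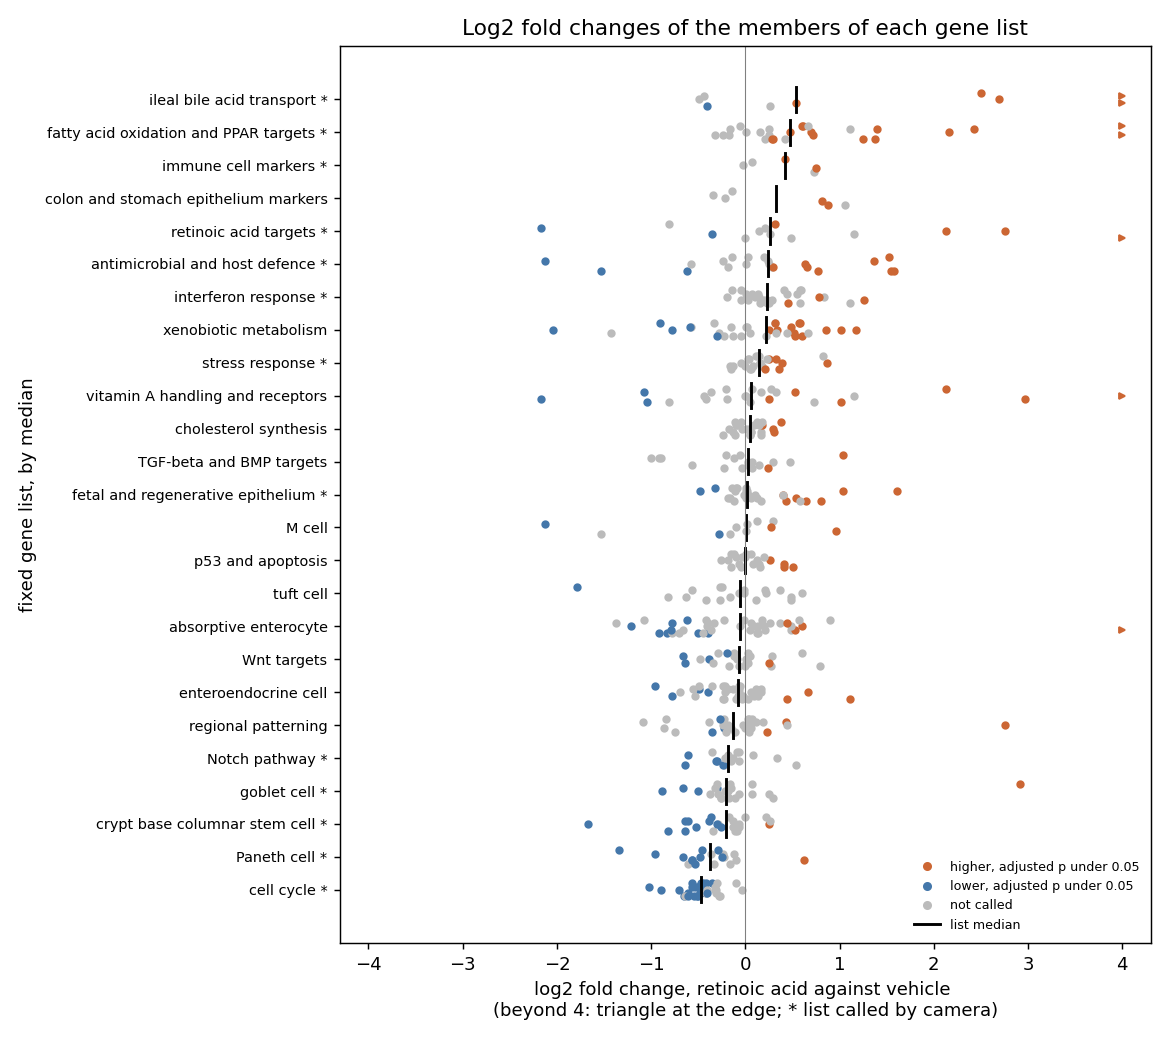
Log2 fold changes (horizontal axis) of the tested members of 25 gene lists, each point a gene and each black bar a list median; an asterisk marks a list called by camera with a preset correlation. The cell cycle list has the lowest median (−0.47) and the ileal bile acid list the highest (0.54), and values beyond 4 are drawn as triangles at the edge.

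Among the genes with the largest decreases were 4 better known from stratified epithelium. Krt14, a basal keratin, went from 2.06 ± 0.726 to 0.264 ± 0.13 CPM (SD, n = 3; log2 fold change −2.98, SE 0.46). Lor, which encodes loricrin, went from 239 ± 60 to 52 ± 28.5 CPM (−2.19, SE 0.26). Tgm1, a transglutaminase, and Krt6a, a keratin, also fell (−1.89 and −1.85), and the adjusted p of Tgm1 was 0.0171 and was as high as 0.0846 (without retinoic acid library 1). Its call was also lost without vehicle library 1 or 3 or retinoic acid library 2, and its log2 fold change was −2.99 without retinoic acid library 3. The chemokine gene Ccl20 fell by 2.12 (SE 0.46; −3.31 without retinoic acid library 3), with an adjusted p of 0.00898 here and an FDR of 0.119 in the authors' deposited table. The others were Pik3ap1 (−2.09), a PI3-kinase adaptor, Akr1c14 (−2.06), a steroid dehydrogenase, Cav1 (−2.04), the main protein of caveolae, Cyp2b10, and Slc5a8 (−1.89), a monocarboxylate transporter.

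Markers of other cell types were mostly too low to test. Of 16 mesenchymal genes and of 16 endothelial, glial and red cell genes 3 and 4 passed the filter on low counts, as did 3 of 10 MHC class II genes, and none of these was called (0 adjusted over the list alone). Of 20 leukocyte markers 5 were tested and 2, Cd14 (1.34-fold) and Cd68 (1.69-fold), were higher, with none lower (2 and 0 adjusted over the list alone). Cd14 is a co-receptor for bacterial lipopolysaccharide and Cd68 a lysosomal protein of macrophages; Cd68 was at 7.28 ± 1.42 CPM with retinoic acid (SD, n = 3) and lost its call without some 1 library (adjusted p up to 0.107), and 1 member was higher without vehicle library 1 or retinoic acid library 1 or 2. That list was called higher (adjusted p = 0.0358). The call was lost without vehicle library 1 (0.0967) or retinoic acid library 3 (0.0662), with a block on replicate number (0.0634) and with an estimated correlation (adjusted p = 0.169).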

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

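The added settings, leaving out both libraries numbered 3 and summing gene segments, were chosen after seeing the data. All 1296 called genes kept their direction in each setting in which they were tested. The counts of higher and lower genes stayed within 1.5 times of 736 and 560 with DESeq2 size factors, without a filter, with the filter of 10 counts, with DESeq2's Wald test (785 and 522), with limma-voom (729 and 556), with gene segments summed and without both libraries numbered 3 (922 and 734). Tested against a 1.5-fold change, 77 genes were higher and 22 lower, since the test then asks for a larger change. Leaving out 1 library in turn gave 443 to 978 higher and 289 to 787 lower genes; the highest counts came without retinoic acid library 3, and the cause was not tested.

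The number of lists called was 8 higher and 5 lower. It was 6 to 10 higher and 4 to 6 lower when 1 library was left out. With fry, which does not compare a list with other genes, 9 were higher and 5 lower: the goblet cell list lost its call (adjusted p = 0.505), and vitamin A handling (0.0123, higher) and Wnt targets (0.031, lower) gained one. Without both libraries numbered 3 the fetal (0.247) and leukocyte (0.0526) lists lost theirs and the enteroendocrine list gained one (0.00265, lower). With an estimated correlation camera called 0 higher and 0 lower, with 4 and 3 at an unadjusted p under 0.05; that setting estimates the correlation from few residual degrees of freedom, and the cause was not tested.

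With replicate number as a block 1224 genes were higher and 1052 lower, including all 1296 genes called without it, and 7 lists were higher and 5 lower. The deviations of same-numbered libraries from their group means correlated at 0.128, 0.098 and 0.257, not all over 0.1, so the numbers were not taken to pair the libraries. Every library did correlate best with its own number, which is a hint from the data and not from the design. The leukocyte marker list lost its call under the block (adjusted p = 0.0634), and Axin2 (0.0145) and Lyz1 (0.006) gained one.

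Of 129 named called genes 92 stayed called whichever library was left out, and 124 were called by DESeq2. Tested against a 1.5-fold change, 98 of the 129 lost their call, and 0 of the 36 cell cycle genes were called. Reversals were seen only in results not called in either setting. Apoa4 had log2 fold changes of 0.16, 0.22 and 0.01 without vehicle library 2, retinoic acid library 1 and retinoic acid library 2 (range −0.48 to 0.22 over the libraries left out). Chga had 0.05 without vehicle library 2 (range −0.24 to 0.05), and Ascl2 0.03 without vehicle library 3 (range −0.17 to 0.03). Camera's direction turned for the M cell list without vehicle library 3 (median −0.05), without retinoic acid library 2 (−0.08) and without both libraries numbered 3 (−0.06; range −0.08 to 0.08 over single libraries left out), and for the tuft cell list without vehicle library 2 (median 0, range −0.23 to 0.02). The TGF-beta and BMP list turned without vehicle library 2 (median 0.05), without retinoic acid library 3 (0.02), without both libraries numbered 3 (−0.06) and with fry (0.03; range −0.11 to 0.05 over single libraries left out). The cause of these turns was not tested.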

Other observations

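The gene lists of this part were written after the called genes had been seen. The LXR, NRF2 and squamous lists left out genes already noticed, and their tests were set before their members' values were looked at. The tests of enterocyte genes, of the squamous list with noticed genes put back, of these lists with 1 library left out and of cell cycle genes with library total as a term were chosen only after the results were seen.

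Genes of the antioxidant response controlled by the transcription factor NRF2 were higher with retinoic acid. Of 19 tested members of a list with no gene in common with the fixed lists, 15 rose and none fell. Srxn1, sulfiredoxin, had 257 ± 6.08 CPM with vehicle and 478 ± 17.6 CPM with retinoic acid (SD, n = 3; log2 fold change 0.90, SE 0.06). The glutathione synthesis genes Gclm and Gclc had log2 fold changes of 0.85 and 0.69, glutathione reductase (Gsr) 0.74 and thioredoxin reductase (Txnrd1) 0.51. Camera gave p = 1.21e-16 for the list, and p = 0.00729 with an estimated correlation. A rise of NRF2 targets as a group is consistent with this test, as a hypothesis found in the same data; Nqo1 and Hmox1 had drawn attention to it. Whether NRF2 itself was more active was not measured.

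The higher bile acid genes were Fabp6, Fgf15, Slc51a, Slc51b and Abcc3. Of them, Fabp6, Fgf15, Slc51a and Slc51b are known targets of FXR, a nuclear receptor that works as a dimer with RXR. A trend with GC content and transcript length was weak over 13528 genes (SD 0.031 on the log2 scale, from −0.41 to 0.06; 0.92% of the variance) and removing it left the median log2 fold change of the 5 genes at 2.67, from 2.69, which argues against it as the whole cause. The 41 tested enterocyte genes did not rise as a group: 8 were lower (7 to 17 with 1 library left out) and 4 higher (3 to 5). Without a filter on low counts 16 of 42 were lower and 9 higher. These counts argue against a general gain of enterocyte maturity as the whole cause, but they were known when the test was chosen. A gain limited to some enterocyte genes, such as Fabp1, Fabp2 and Mttp, which rose, is not excluded. Not all lipid-handling genes of that list rose, as Apob fell (−0.40, SE 0.08). If retinoic acid or a product of it acted through RXR on several of its partners, targets of LXR, another partner, might rise too. Their median log2 fold change was 0.25 and camera gave p = 0.00127 (0.0577 with an estimated correlation). Of these, 6 of 14 were higher (3 without vehicle library 1 or retinoic acid library 2), among them Lpcat3 (0.74), Scd2 (0.78) and Abcg1 (0.95), and none was lower. The other members were not called and lay between Arl4c (−0.38) and Abca1 (0.93), with Abcg5 (0.09) and Abcg8 (0.04) near 0. A rise across several RXR partners stays open, as do direct effects on each gene. LXR was the only other partner with a list written for this question. In the fixed list with targets of PPAR, also an RXR partner, 14 of 27 members were higher and none lower. Drug-metabolising genes went both ways, with 12 of 33 higher and 5 lower, Cyp2b10 and Cyp2c55 among the latter. Those fixed lists had been seen before the question was put, so they are no test of it.

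The lower cell cycle genes had a median log2 fold change of −0.45 after the same weak trend with GC content and length was removed, against −0.47 before. With the log2 of each library's total as a term beside treatment it was −0.39 (−0.47 to −0.33 with 1 library left out), and 9 of the 36 genes were called lower (2 without vehicle library 1 or 2 or retinoic acid library 2, and 15 without retinoic acid library 3), against 24 without the term, in a fit with fewer residual degrees of freedom. That trend and library size are therefore argued against as the whole cause, though library size is not excluded as a part of it. Thinning every library to 14919144 counts gave −0.46, but thinning leaves expected CPM ratios as they are and so decides nothing on library size. An effect of the treatment on proliferation, or on the share of dividing cells, may account for it and was not tested further.

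The lower genes Krt14, Lor, Tgm1 and Krt6a are known from squamous epithelium. Skin-like squamous tissue in the vehicle cultures was argued against. Krt1, Krt5, Krt10 and Krt14 together reached between 0.0216 and 0.0321 of the CPM of Lor in the vehicle libraries. Skin is taken to hold these keratins at levels at least like that of loricrin, which was not measured here. Squamous tissue of other kinds was not tested. A list of 33 other squamous genes, 16 of them tested, had 3 higher and 3 lower (1 and 1 without vehicle library 1 or retinoic acid library 1, 2 and 1 without vehicle library 2, 1 and 4 without vehicle library 3, and 1 and 2 without retinoic acid library 2), a median log2 fold change of −0.07 (−0.13 to −0.03 with 1 library left out) and a camera p of 0.639 (0.188 to 0.875). With the 4 noticed lower genes put back the p was 0.0288 (0.0756 with an estimated correlation) and the median −0.16, but with Sprr1a, a cornified envelope gene that was higher, put back too they were 0.139 (0.181) and −0.13. Whether a squamous programme fell as a whole cannot be told apart from a change in a few of its genes, because the first test left out called genes and the others turn on which of them are put back.

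Only 10 splits of the 6 libraries into groups of 3 exist, too few for a share under 0.05. The real split called 1296 genes and the highest of the other splits 0, by edgeR. For lists, the real split called 13 and the highest of the others 7. In both, 1 of the 10 splits, the real one, reached its value.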
